A study of Homo sapiens with 6 samples.

How the data were processed

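Poly(A) RNA of A549 cells was selected with oligo(dT) beads, primed with random primers and sequenced per the labels, with 3 libraries after DMSO and 3 after Japoflavone B. The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1, DESeq2 without a version and the build GRCh38, and state neither the role nor the order of the tools, nor the annotation release or the strand setting. The deposited table lists 61806 Ensembl genes, of which 20417 have no symbol, and holds for each library the raw counts per gene as whole numbers that the authors made. The deposited FPKM columns were computed by the authors from these counts, the exonic gene size and the column total, rounded to 2 decimals; recomputed values differed by at most 0.005. The exonic gene sizes in the deposited table are in bases, per the file headers.

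The groups were taken from the treatment labels; the treated libraries and their columns are titled LE-532, a code that the labels do not explain, and their treatment label is Japoflavone B. The tests had been planned on log2(FPKM + 1) with limma, with edgeR on the counts if whole-number counts were present, and since they were, the edgeR branch was used. Genes were filtered by filterByExpr with a minimum count of 10 and a minimum total of 15, which kept 16082 genes that hold 99.8% or more of the counts of each library. Libraries were scaled by trimmed mean of M-values factors, which ran from 1.03 to 1.04 for DMSO and from 0.957 to 0.970 for Japoflavone B. Counts were fitted with edgeR 4.0.16 (quasi-likelihood, group as the single term) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A 2-fold change is an absolute log2 fold change of at least 1. Values of single genes of the title were also compared by an exact two-sided permutation test. Replicate numbers did not pair the libraries: deviations of a DMSO library from its group mean correlated with those of the Japoflavone B library of the same number at 0.013, -0.004 and -0.045 across genes.

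The 39 gene lists with 1160 entries, the naming rule and the tests were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM (counts scaled to the library total times the trimmed-mean factor, prior count 2) with a preset correlation of 0.01 and a variance trend, adjusted by Benjamini-Hochberg over the 37 lists with at least 5 tested members; an estimated correlation and fry were run beside it. The rule names the genes of the title, the 12 genes with the highest and the 12 with the lowest fold change among those with a symbol other than a clone name, past the threshold, with at least 5 FPKM in the higher group and no overlap between groups, up to 4 members of each list by adjusted p among those with at least 1 FPKM, and up to 3 members of the quality and cell type lists by FPKM. It gave 159 genes, of which some are not reported here; any other gene named was chosen after its values were seen. Terms of GO and KEGG as the deposited table assigns them to genes were tested the same way, for terms with 15 to 400 tested genes.

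Alternatives were no filter, a mean of at least 2 FPKM, the size factors of DESeq2, upper-quartile scaling, DESeq2 1.42.0 as the test, quasi-likelihood without an abundance trend and with robust estimation, the replicate number as a block, limma on log2 of FPKM + 1, + 0.5 and + 0.1 and of TPM + 1, and each of the 6 libraries left out in turn. Those chosen after seeing the data were library totals alone, protein-coding genes by the classes of GENCODE 29 since the table gives no class, and mitochondrial genes left out. A further one was the p53 list without genes of the ATF4, immediate-early, p38 and JNK and mesenchymal lists. The workflow was tested on simulated data: of 100 genes changed 1.5-fold 66% were recovered and of 100 changed 2-fold 80%, while 11 of 15802 unchanged genes were called, 5.1% of 216 calls, and 2 of 2 changed lists but 0 of 8 unchanged lists were called. Depth was 15298531 to 21744407 counts per library. Ratios for genes with 3 or fewer DMSO counts carry exact 95% binomial intervals, which cover counting error only, since reads carry no molecular identifiers that the labels mention.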

Results

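RNA was measured in A549 cells, a human lung adenocarcinoma line, after treatment with Japoflavone B or with its solvent DMSO. The labels give 3 libraries per group, a treatment of 24 h that followed 24 h of seeding, and a dose of 40 whose unit they do not state. The title calls the compound a PARP1 inhibitor and names GSDME and p38 among others, so the comparison asks how the mRNA of treated cells differed from that of solvent cells, with those genes in view. The DMSO libraries held 20826289, 21744407 and 15298531 gene counts and the Japoflavone B libraries 19822366, 15733769 and 18437272. Pearson correlations of log2 CPM, scaled by the trimmed-mean factors, were 0.990 to 0.992 within groups and 0.926 to 0.931 between them. The first principal component of the same values, which separated the groups, held 84.3% of the variance. Mitochondrial genes took 4.36% ± 0.371 of counts after DMSO and 8.43% ± 0.128 after Japoflavone B (SD, n = 3). The 10 most abundant genes took 6.26% ± 0.0837 and 9.92% ± 0.111 of counts (SD, n = 3).

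Most genes tested differed after Japoflavone B: of 16082, 5577 were higher and 5686 lower (edgeR quasi-likelihood test, Benjamini-Hochberg), together 70%. In FPKM, which are scaled by library totals without the trimmed-mean factors, the groups did not overlap in 11509 genes, or 71.6%, where chance gives 10%. The shift between these scalings, given below, is part of that count. A change of at least 2-fold was found in 1555 genes that rose and 2419 that fell. Among the lists described below, all 60 tested genes of mitosis and 32 of 37 NRF2 targets fell, while 39 of 43 p53 targets, 32 of 36 ATF4 targets and 25 of 27 immediate-early genes rose. Of the genes past the threshold, 49.5% were higher. With library totals alone as the scaling in the same test the share was 42.4%, and the median shift per gene was -0.10 log2. Limma on log2(TPM + 1) changes the test, the unit and the genes tested (14187) together. There the share was 35.4%, and the median shift per gene was -0.21 log2. The labels do not say whether the libraries come from separate cultures, so the p-values measure the spread between these libraries only. FPKM below are means ± SD over n = 3 libraries and are scaled by library totals, whereas fold changes use trimmed-mean factors, so that the ratio of FPKM differs slightly from the fold.

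Among genes of the title, PARP1 fell and GSDME rose, both by less than 2-fold. PARP1 (ENSG00000143799, chromosome 1, 226360210 to 226408154, GRCh38), a DNA damage sensor that makes poly(ADP-ribose), fell from 16.4 ± 0.0551 to 12.3 ± 0.108 FPKM, log2 fold change -0.31 ± 0.05 (SE; edgeR adjusted p = 3.15e-06). GSDME (ENSG00000105928, chromosome 7, 24698355 to 24757940), the gene of a pore-forming gasdermin, rose from 4.83 ± 0.313 to 5.29 ± 0.0917 FPKM, log2 fold change 0.24 ± 0.07 (adjusted p = 0.00487). MAPK14 (ENSG00000112062, chromosome 6, 36027677 to 36111236), the p38 alpha kinase gene, had 8.18 ± 0.0656 and 7.32 ± 0.302 FPKM, log2 fold change -0.06 ± 0.07, which did not pass (adjusted p = 0.437). The exact two-sided permutation test of the 6 log2 CPM values gave p = 0.1 for each of these 3 genes, the smallest p that 3 against 3 allows. The call for GSDME was lost and MAPK14 was called lower under 5 alternatives each that scale by library totals, as FPKM or as TPM; GSDME then had a log2 change of 0.02 to 0.13 and MAPK14 of -0.26 to -0.14.

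**Figure D1:**
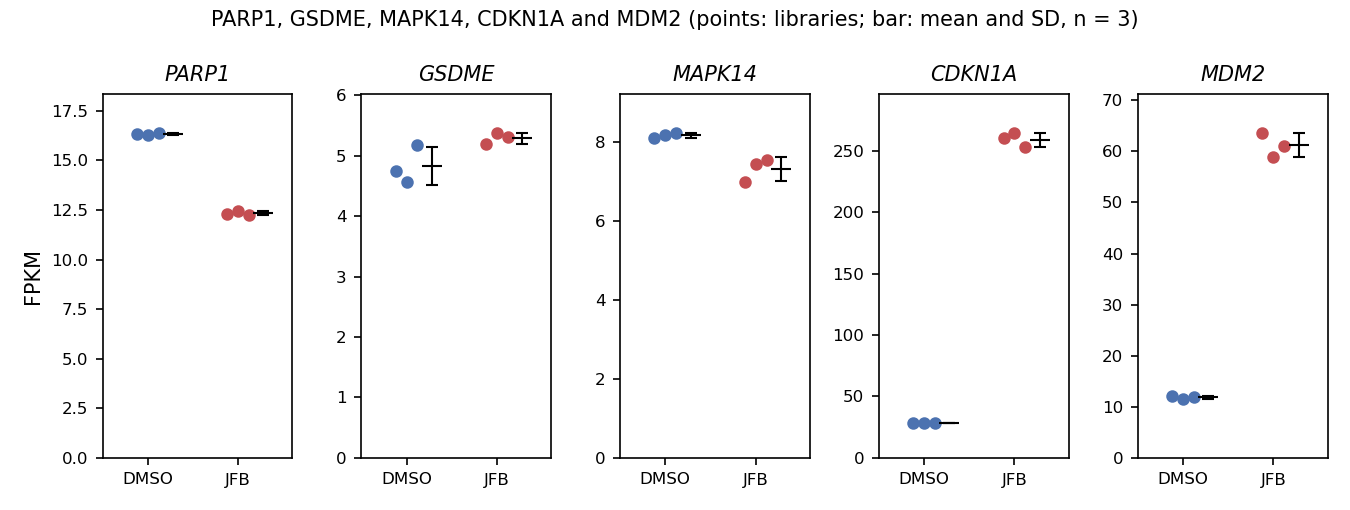
Expression (FPKM, axis from 0) of PARP1, GSDME and MAPK14 and of the p53 targets CDKN1A and MDM2 in 3 DMSO and 3 Japoflavone B (JFB) libraries; points are libraries, the bar gives mean and SD. PARP1 fell from 16.4 to 12.3 FPKM while CDKN1A rose from 28.5 to 259 FPKM.

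p53 target genes were higher as a group. Of 43 tested p53 targets, 39 rose and 2 fell, with a median log2 fold change of 1.33 (camera adjusted p = 6.92e-16, and adjusted p = 0.0117 with an estimated correlation). The counts adjusted over the list alone were also 39 and 2. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 28.5 ± 0.294 to 259 ± 5.7 FPKM, 9.78-fold higher (log2 SE 0.05; edgeR adjusted p = 1.39e-26). MDM2, a ubiquitin ligase gene, was 5.55-fold higher, GDF15, a secreted stress cytokine, 15.9-fold higher, and GADD45A, a growth arrest gene, 11.9-fold higher. The 2 members that fell were APAF1, the apoptosome scaffold (-0.83 log2), and PLK2, a polo-like kinase (-1.01 log2). Here and below, members outside the naming rule that make up a count of 5 or fewer were named after their values were seen.

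Cell division genes fell. All 60 tested genes of mitosis and G2/M fell, with a median log2 fold change of -2.21 (camera adjusted p = 1.53e-31; adjusted p = 0.00771 with an estimated correlation). Among them TOP2A, the topoisomerase that untangles chromosomes, fell from 223 ± 13 to 28.5 ± 1.17 FPKM (7.32-fold lower), the proliferation marker MKI67 from 44.1 ± 5.16 to 4.84 ± 0.311 FPKM (8.48-fold lower), and the mitotic regulators PLK1 and CCNA2 were 7.42-fold and 7.59-fold lower. Of 49 DNA replication and G1/S genes, 48 fell and 1 rose (median -1.28 log2; camera adjusted p = 1.39e-18, and adjusted p = 0.00771 with an estimated correlation). The ribonucleotide reductase subunit RRM2 was 6.09-fold lower and the replicative helicase subunits MCM3 and MCM6 were 6.89-fold and 6.2-fold lower. The epigenetic replication factor UHRF1 was 7.18-fold lower. The member that rose was the licensing factor CDT1 (0.44 log2). Homologous recombination and Fanconi genes also moved down, with 37 of 45 lower, 4 higher and a median of -0.81 log2 (camera adjusted p = 1.66e-08; adjusted p = 0.0974 with an estimated correlation). BRCA1 was 3.39-fold lower, FANCI 2.77-fold lower, the nuclease EXO1 4.21-fold lower and RAD51AP1 5.15-fold lower. The members that rose were PALB2, FANCE, FANCF and MUS81, by 0.41, 1.07, 0.89 and 0.48 log2.

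Genes of the cell death and signalling routes that the title names moved in both directions. In the pyroptosis machinery 4 of 14 tested members rose and 7 fell (median -0.15 log2; camera adjusted p = 0.532). NINJ1, which ruptures the plasma membrane, was 1.68-fold higher and the cytokine gene IL18 1.29-fold higher (a call lost as TPM, adjusted p = 0.0522), whereas HMGB1, a nuclear protein released by dying cells, was 2.98-fold lower and the inflammasome regulator CARD8 2.32-fold lower. The other 2 that rose were GSDME and NLRP1, the latter from 11 counts over the DMSO libraries to 79 over the treated ones. HMGB1 has many processed pseudogenes, and reads shared with them were not resolved. In the apoptosis machinery 14 of 32 rose and 12 fell, with a median of 0.05 log2 that turned to -0.05 with library totals and -0.11 as TPM (camera adjusted p = 0.627). BBC3, the pro-apoptotic gene of PUMA, was 5.46-fold higher, the anti-apoptotic genes MCL1 and BCL2L1 were 3.1-fold and 3.14-fold higher, and BIRC5, the gene of survivin, was 4.01-fold lower. In the PARP family list 9 of 17 fell and 5 rose (median -0.31 log2, camera adjusted p = 0.459). That list also holds PARG, ADPRS, HPF1 and XRCC1, related genes that are not PARPs. PARP14 and PARP9 were 3.85-fold and 2.73-fold lower, while PARP6 and the tankyrase gene TNKS2 were 2.18-fold and 1.58-fold higher; the other 3 that rose were TNKS, ADPRS and XRCC1, by 0.66, 0.90 and 0.44 log2. In the p38 and JNK pathway 11 of 25 rose and 8 fell, with a median of 0.16 log2 that turned to -0.06 as TPM (camera adjusted p = 0.384). Of the kinases upstream of p38, MAP2K3 was 2.16-fold higher and MAP2K6 4.34-fold lower, and the transcription factor gene MEF2D was 2.67-fold higher. For these 4 lists the counts adjusted over the list alone were identical, and the camera p stayed above 0.05 with an estimated correlation (adjusted p = 0.646, 0.797, 0.568 and 0.544 in that order).

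Immediate-early genes and the integrated stress response were higher. Of 27 AP-1 and immediate-early genes, 25 rose and 1, JUND, fell by 0.28 log2 (list median 1.17 log2; camera adjusted p = 8.94e-12; adjusted p = 0.083 with an estimated correlation). EGR1, a transcription factor induced by growth factors and stress, went from 0.403 ± 0.0815 to 37.7 ± 4.01 FPKM (97.6-fold higher; log2 SE 0.12; edgeR adjusted p = 2.34e-25). DUSP1 and DUSP5, phosphatases of MAP kinases, were 7.21-fold and 6.1-fold higher, and the matricellular gene CCN1 was 7.17-fold higher. Of 36 ATF4 targets, 32 rose and 4 fell (median 1.39 log2; camera adjusted p = 3.95e-12; adjusted p = 0.0517 with an estimated correlation). The secreted glycoprotein STC2 was 11.9-fold higher, the transcription factor ATF3 14.3-fold higher, the pseudokinase TRIB3 4.77-fold higher and the mitochondrial folate enzyme MTHFD2 3.92-fold higher. Those that fell were ATF5, PSPH, SLC7A5 and XPOT, at -1.36, -0.53, -0.14 and -0.47 log2. Of 25 ER chaperone and unfolded protein response genes, 19 rose and 2 fell (median 0.51 log2; camera adjusted p = 1.84e-05; adjusted p = 0.247 with an estimated correlation). DNAJB9 was 5.66-fold higher, the stress sensor ERN1 3.96-fold higher, HSPA5, the gene of the chaperone BiP, 2.12-fold higher and calnexin, CANX, 1.95-fold higher; those that fell were CALR (-0.51 log2) and CRELD2 (-0.44 log2).

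**Figure D2:**
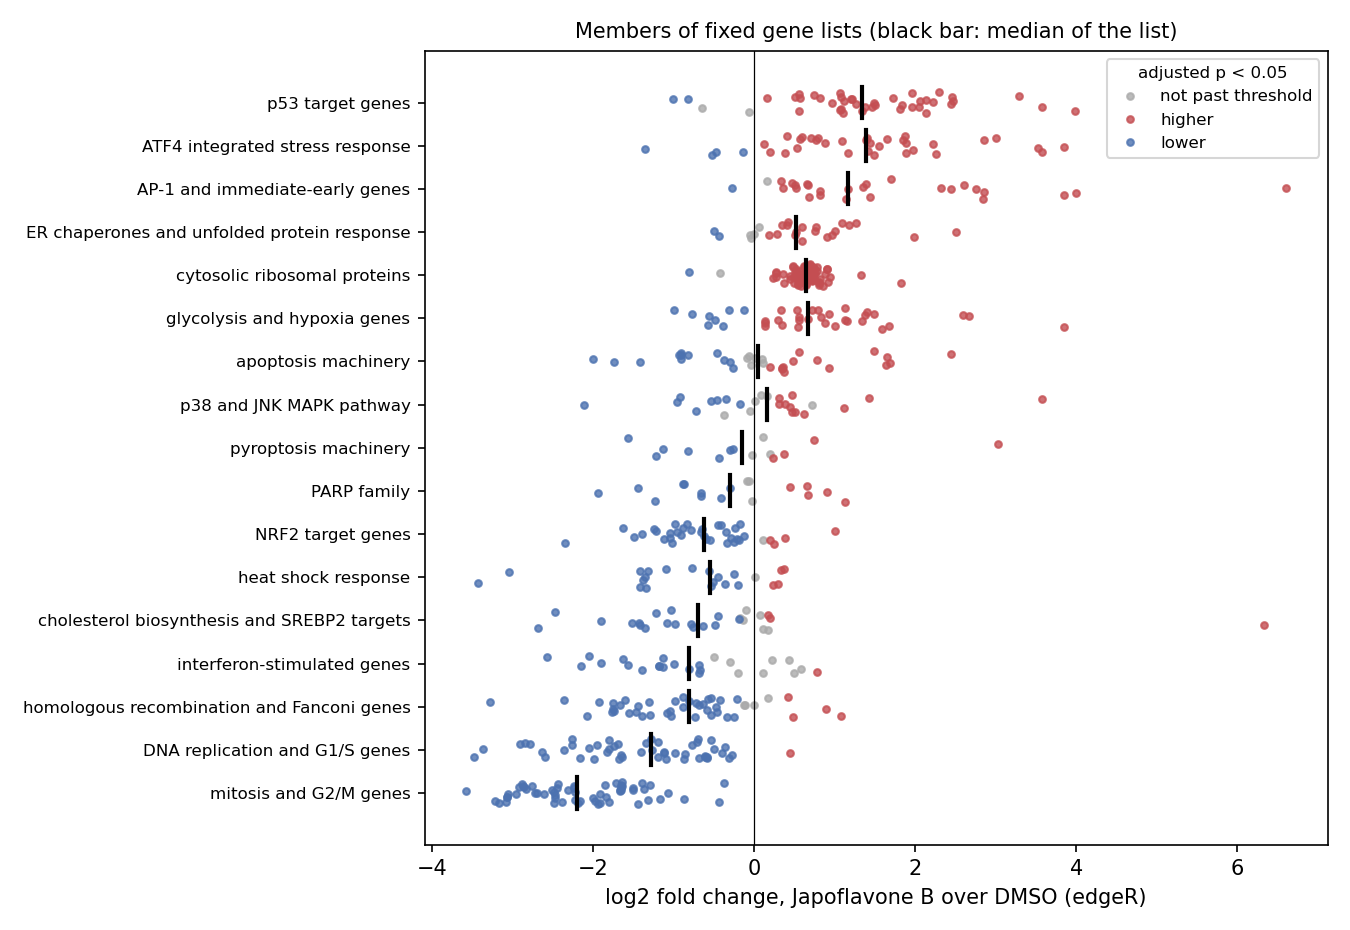
Log2 fold change (Japoflavone B over DMSO, edgeR) of each tested member of 17 of the fixed gene lists; red points rose and blue points fell at an adjusted p under 0.05, grey points did not pass, and the black bar is the median of the list. List medians run from -2.21 for mitosis and G2/M genes to 1.39 for ATF4 targets; the medians of the apoptosis list (0.05) and of the p38 and JNK list (0.16) turn negative as TPM, and that of the apoptosis list also with library totals.

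NRF2 targets, which A549 cells express at high levels, fell. Of 37 tested, 32 fell and 4 rose (median -0.63 log2; camera adjusted p = 1.66e-08; adjusted p = 0.268 with an estimated correlation). The glutathione peroxidase GPX2 fell from 62.4 ± 2.39 to 11.5 ± 1.74 FPKM (5.09-fold lower), the aldo-keto reductases AKR1C2 and AKR1C3, which share much of their sequence, were 2.82-fold and 3.09-fold lower, and ferritin light chain, FTL, which has many pseudogenes, was 2.63-fold lower. Those that rose were HMOX1, SRXN1, SLC7A11 and SLC3A2, by 1.00, 0.25, 0.20 and 0.38 log2; HMOX1 degrades haem, and SLC7A11 with SLC3A2 forms the cystine importer. Of 20 other antioxidant enzymes, 16 fell and 1, GPX1, rose by 0.53 log2 (list median -0.51 log2; camera adjusted p = 0.00384; adjusted p = 0.544 with an estimated correlation). SOD1 was 1.5-fold lower, the mitochondrial proteins PRDX3 and TXNRD2 1.43-fold and 2.41-fold lower, and GPX8 1.54-fold lower. Heat shock genes moved the same way, with 17 of 22 lower and 4 higher (median -0.55 log2; camera adjusted p = 4.14e-05; adjusted p = 0.279 with an estimated correlation). The near-identical copies HSPA1A and HSPA1B were 10.8-fold and 8.24-fold lower, DNAJA1 was 2.67-fold lower and HSP90AA1 2.53-fold lower; those that rose were HSPA4L, HSP90AB1, DNAJB6 and BAG3, by 0.33, 0.30, 0.37 and 0.23 log2. Of 5 metallothionein and zinc genes, 3 rose and 2, MT1A and MT1F, did not pass (median 0.39 log2; camera adjusted p = 0.249): the zinc exporter SLC30A1 was 2.99-fold higher, MT1X 2.11-fold higher and MT2A 1.31-fold higher, while MT1A stood at -0.67 log2 (edgeR adjusted p = 0.149). The calls of MT2A and MT1A changed in the 4 alternatives that used log2 of FPKM or TPM, where MT2A no longer passed and MT1A was called lower. Of 8 aryl hydrocarbon receptor targets, 3 rose and 4 fell (median -0.02 log2; camera adjusted p = 0.476). CYP1B1 was 6.14-fold lower, ALDH3A1 2.9-fold lower and NQO1 2.18-fold lower, SLC7A5 stood at -0.14 log2, and the members that rose were the growth factor EREG (4.91-fold higher), TIPARP (0.57 log2) and NFE2L2 (0.16 log2).

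Lipid synthesis genes fell and glycolysis and hypoxia genes rose. Of 26 cholesterol biosynthesis genes and SREBP2 targets, 17 fell and 3 rose (median -0.70 log2; camera adjusted p = 7.09e-05; adjusted p = 0.152 with an estimated correlation). INSIG1 was 3.75-fold lower, HMGCS1 2.69-fold lower and FDPS 2.57-fold lower. Among those that rose were MSMO1 (0.17 log2) and NPC1L1, which had 1 count over the DMSO libraries and 97 over the treated ones, a ratio of 104 per library total with an exact counting interval of 18.2 to 4150. Of 17 fatty acid synthesis genes, 13 fell and 1, ACLY, rose by 0.16 log2 (list median -0.66 log2; camera adjusted p = 1.92e-04; adjusted p = 0.097 with an estimated correlation). FADS2 was 4.65-fold lower, FASN 2.3-fold lower, SCD 1.94-fold lower and their regulator SREBF1 2.17-fold lower. Of 37 glycolysis and hypoxia genes, 29 rose and 8 fell (median 0.67 log2; camera adjusted p = 4.14e-05; adjusted p = 0.455 with an estimated correlation). ANGPTL4 was 6.33-fold higher, BHLHE40 3.2-fold higher, NDRG1 2.99-fold higher and the glucose transporter SLC2A1 2.52-fold higher. Nuclear-encoded oxidative phosphorylation genes were split, with 18 of 53 higher and 19 lower (median -0.01 log2; camera adjusted p = 0.808); NDUFS5 and NDUFB10 were 1.75-fold and 1.54-fold lower, and UQCRC1 and UQCRB 1.54-fold and 1.41-fold higher.

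Interferon-stimulated genes fell, whereas inflammatory cytokine genes were divided. Of 25 interferon-stimulated genes, 16 fell and 1, IRF7, rose by 0.78 log2 (list median -0.81 log2; camera adjusted p = 0.00174; adjusted p = 0.184 with an estimated correlation). OAS3 was 2.64-fold lower, IFI35 4.15-fold lower and HERC6 3.75-fold lower. Of 23 NF-kB and cytokine genes, 8 rose and 9 fell; the median was -0.22 log2, while the mean of 0.27 and the camera direction were positive (adjusted p = 0.709). CXCL8, the neutrophil attractant interleukin-8, went from 0.997 ± 0.186 to 18.9 ± 1.76 FPKM (20.8-fold higher), NFKB2 and LIF were 2.82-fold and 2.4-fold higher, and TNFAIP2 was 2.41-fold lower. Of 20 senescence-associated secretory genes, 10 rose and 7 fell, or 8 adjusted over the list alone (median 0.19 log2; camera adjusted p = 0.0609). That list passed when DMSO replicate 1, 2 or 3 was left out (adjusted p = 0.0402, 0.0360 and 0.0150) and when Japoflavone B replicate 1 or 3 was left out (0.0333 and 0.0424). The growth factor gene AREG was 8.62-fold higher and STC1 7.83-fold higher.

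Epithelial genes were mostly lower: 11 of 18 fell and 4 rose (median -0.49 log2), and the list did not pass (camera adjusted p = 0.0663; 0.0456 without DMSO replicate 1). Keratins KRT8 and KRT18, which have many pseudogenes, were 2.86-fold and 3.32-fold lower, E-cadherin, CDH1, fell from 11.7 ± 0.695 to 3.03 ± 0.215 FPKM (3.6-fold lower), and the tight junction gene CLDN2 was 10.6-fold lower. Those that rose were OCLN, DSP, MARVELD2 and CDH3, by 1.17, 0.18, 1.44 and 4.98 log2. Of 33 mesenchymal and TGF-beta genes, 12 rose and 13 fell; the median of -0.04 log2 and the mean of -0.08 were negative and the camera direction was up (adjusted p = 0.999). LOXL2, which crosslinks collagen, was 3.42-fold higher, while TGFB2 and COL5A1 were 5.59-fold and 3.51-fold lower. Of 24 YAP and TEAD targets, 10 rose and 11 fell, with a median of 0.01 log2 that turned negative with upper-quartile scaling, library totals and TPM (-0.01, -0.10 and -0.19; camera adjusted p = 0.808); NT5E was 4.77-fold higher and IGFBP3 3.69-fold lower.

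Genes of translation rose. Of 76 cytosolic ribosomal protein genes, 74 rose and 1, RPS26, fell by 0.81 log2, and the list median was 0.64 log2 (camera adjusted p = 1.39e-18; adjusted p = 0.452 with an estimated correlation). RPL12 rose from 266 ± 10.1 to 469 ± 24.2 FPKM (1.89-fold higher), RPS27 was 1.87-fold higher, RPL11 1.76-fold higher and RPL21 3.53-fold higher; reads that these genes share with their pseudogenes were not resolved. Of 42 ribosome biogenesis genes and MYC targets, 25 rose and 6 fell (median 0.24 log2; camera adjusted p = 0.0101; adjusted p = 0.435 with an estimated correlation), a call also lost in 4 other alternatives (adjusted p = 0.0502 to 0.115). DDX21 was 2.45-fold higher, NOB1 2.67-fold higher, RRP12 2.23-fold higher and BOP1 2.07-fold higher. Of 32 proteasome subunits, 16 fell, 6 rose and 10 did not pass, and the list did not pass (median -0.15 log2; camera adjusted p = 0.0609; adjusted p = 0.646 with an estimated correlation). The proteasome list passed without DMSO replicate 1 or 2 or Japoflavone B replicate 2 (adjusted p = 0.0137, 0.0448 and 0.0482). PSMD11, PSMD1, PSMC3 and PSMA3 were 1.8-fold, 1.69-fold, 1.57-fold and 1.55-fold lower. Of 46 autophagy and lysosome genes, 22 rose (21 adjusted over the list alone) and 10 fell, with a median of 0.13 log2 that turned to -0.07 as TPM (camera adjusted p = 0.118); ATG4A and MAP1LC3B, genes of autophagosome formation, were 2.68-fold and 1.71-fold higher, and the lysosomal enzymes GLA and CTSZ 2.97-fold and 1.63-fold lower. Of 24 ferroptosis regulators, 11 rose and 10 fell, with a median of 0.05 log2 that turned to -0.05 with library totals and -0.15 as TPM (camera adjusted p = 0.476). The polyamine enzyme SAT1 and the transferrin receptor TFRC were 3.19-fold and 2.01-fold higher, and VDAC3 was 2.03-fold lower.

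Transcripts of the mitochondrial genome did not move together. Both mitochondrial ribosomal RNAs rose, MT-RNR1 5.33-fold and MT-RNR2 3.59-fold (edgeR adjusted p = 1.73e-24 and 1.49e-22), and their share of counts went from 1.06% ± 0.0364 to 3.60% ± 0.131 (SD, n = 3). The rest of the mitochondrial share went from 3.30% ± 0.337 to 4.83% ± 0.0723 (SD, n = 3). Of 13 mRNAs, 8 rose, among them MT-CO1 (1.9-fold higher), MT-CO2 (1.77-fold higher) and MT-ND4 (2.21-fold higher). MT-CO3 fell from 5673 to 3349 FPKM (1.58-fold lower; edgeR adjusted p = 9.37e-12), and MT-ND3 and MT-ATP6 fell by 0.12 and 0.14 log2. MT-ND2 (0.03 log2, and -0.07 with library totals and -0.18 as TPM) and MT-ATP8 (-0.13 log2) did not pass. The median of the mRNAs was 0.36 log2 (camera adjusted p = 0.0307; adjusted p = 0.646 with an estimated correlation), and the call was also lost in 6 other alternatives (adjusted p = 0.0508 to 0.103). The pairs MT-ATP8 with MT-ATP6 and MT-ND4L with MT-ND4 overlap in sequence.

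**Figure D3:**
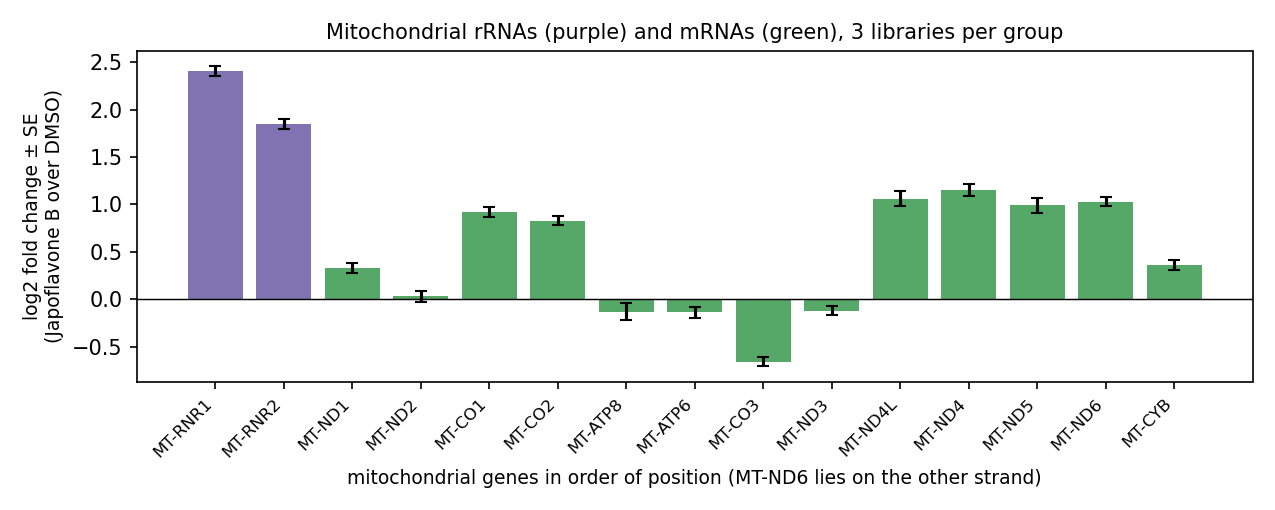
Log2 fold change ± SE (Japoflavone B over DMSO, edgeR, 3 libraries per group) of the mitochondrial ribosomal RNAs (purple) and mRNAs (green) in order of position. MT-RNR1 (2.41) and MT-RNR2 (1.85) lie highest and MT-CO3 (-0.66) lowest; MT-ND2 (0.03) changes sign with library totals and TPM.

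Among genes with a symbol other than a clone name that passed the threshold with at least 5 FPKM in the higher group and no overlap between groups, the strongest increases were those of EGR1, TMEM158, SDCBP2, RRAD, CXCL8, GDF15, ATF3, TSC22D3, CD82 and GADD45A and of a pair of genes with almost no DMSO counts. TMEM158, a membrane protein gene induced by RAS, went from 0.853 ± 0.162 to 25.4 ± 1.58 FPKM (32.4-fold higher). TSC22D3, which encodes a glucocorticoid-induced leucine zipper protein, went from 1.67 ± 0.215 to 20.8 ± 0.354 FPKM (13.3-fold higher), and the tetraspanin gene CD82 was 12.6-fold higher. SDCBP2 and RRAD were 42.4-fold and 29.2-fold higher, from 21 and 17 counts over the 3 DMSO libraries. RPL36A-HNRNPH2, a read-through gene that overlaps RPL36A and HNRNPH2, had 3 counts over the DMSO libraries and 307 over the treated ones, a ratio of 110 per library total with an exact 95% counting interval of 37.2 to 535. The long noncoding RNA LINC01629 had 3 and 275 counts, a ratio of 98.2 with an interval of 33.3 to 479; these intervals cover counting error only. Under the same limits, the strongest decreases were those of CACNG6, CPLX2, CDKN2C, IGFBP1, SPC25, HJURP, LXN, HSPA2, E2F8, HSPA1A, CLDN2 and DCDC2, from 18-fold lower for the calcium channel subunit CACNG6 to 10.5-fold lower for the doublecortin gene DCDC2. CPLX2, a regulator of vesicle exocytosis, fell from 234 ± 2.66 to 13.8 ± 0.331 FPKM (15.7-fold lower; log2 SE 0.05; edgeR adjusted p = 1.62e-28). CDKN2C, the gene of the CDK4 and CDK6 inhibitor p18, fell from 10.7 ± 0.509 to 0.64 ± 0.0557 FPKM (15.5-fold lower). SPC25 and HJURP, genes of the kinetochore and of centromeric chromatin, were each 12-fold lower, the cell cycle repressor E2F8 was 11.2-fold lower, the carboxypeptidase inhibitor LXN 11.6-fold lower, IGFBP1 12.6-fold lower and HSPA2 11.5-fold lower.

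Markers of other cell types did not move together. Of 6 alveolar type II markers, ABCA3 (2.32-fold higher), ETV5 (1.48-fold higher) and LAMP3 (1.33 log2) rose and HHIP fell by 0.63 log2, with LPCAT1 at -0.02 log2 and called lower only as TPM (list median 0.27 log2; camera adjusted p = 0.343). Fibroblast markers had 3 of 7 lower, or 2 adjusted over the list alone (median -0.23 log2; camera adjusted p = 0.343): COL1A1, also in the mesenchymal list, went from 4.64 ± 0.295 to 0.473 ± 0.0586 FPKM, FBLN1 was 1.18-fold lower and COL3A1 stood at -1.05 log2. Of hepatocyte-type secreted proteins 4 of 6 fell (median -1.56 log2; camera adjusted p = 0.0218; adjusted p = 0.466 with an estimated correlation): the fibrinogen chains FGA, FGB and FGG were 8.89-fold, 5.32-fold and 7.94-fold lower, and APOH stood at -0.71 log2, while TF rose by 2.08 log2. Of 3 leukocyte markers tested, CD14 fell from 2.53 ± 0.475 to 0.313 ± 0.142 FPKM, ITGAM fell by 1.49 log2 and LCP1 rose from 2 to 69 counts, a ratio of 37.0 with an exact counting interval of 9.86 to 311; the list median was -1.49 and its mean 0.21 log2. Of 2 endothelial markers tested, EGFL7 was 1.28-fold higher, a call that ended in 4 alternatives on log2 FPKM or TPM, and ESAM stood at -0.03 log2 (median 0.17, and -0.01 as TPM). Leukocyte and endothelial lists had fewer than 5 tested members and no set test. Replication-dependent histones had 6 of 13 higher and 3 lower, or 4 lower adjusted over the list alone, with a median of 0.15 log2 (camera adjusted p = 0.512). The median was -0.60 log2 as TPM, an alternative that also changes the genes tested. The 2 medians therefore need not cover the same members. H2BC12, H2BC5 and H2AC6 were 1.42-fold, 2.25-fold and 1.6-fold higher, and those that fell were H2AC13, H3C10 and H4C8, at -2.48, -1.24 and -0.75 log2. Of 9 long noncoding RNAs fixed as a check of RNA quality, GAS5 (2.64-fold higher), SNHG1 (1.72-fold higher) and NORAD (1.52-fold higher) rose and NEAT1 and OIP5-AS1 fell by 0.34 and 0.84 log2, with a median of 0.08 log2 that turned to -0.02 with library totals and -0.07 as TPM (camera adjusted p = 0.525).

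Of the 37 lists with a set test, 8 were called higher and 10 lower, and 3 of these calls, for p53 targets, DNA replication and mitosis, held with an estimated correlation. Adjusted over the list alone, the counts of members also differed from those over all genes for NRF2 targets, with 5 higher in place of 4, and for fatty acid synthesis, with 2 higher in place of 1. Apart from the lists whose count is given above in that form, the others gave identical counts.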

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

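Library totals alone, protein-coding genes alone, mitochondrial genes left out and the shortened p53 list were alternatives chosen after seeing the data. Of 159 named genes, 152 kept direction and side of the threshold under every alternative; besides GSDME and MAPK14, the exceptions were EGFL7, IL18, LPCAT1, MT1A and MT2A, and no result changed sign past the threshold. The number of higher genes ran from 3448 to 5823 and that of lower genes from 3884 to 6467. Log2 of TPM + 1 gave 3448 higher genes against 6281 lower, with a median shift per gene of -0.21 log2 against the main test. It changes test, unit and genes tested together. At least 2-fold higher were 654 genes with a mean of at least 2 FPKM, where fewer genes were tested, 502, 683 and 913 with limma on FPKM + 1, + 0.5 and + 0.1, and 654 with TPM + 1. At least 2-fold lower were 1094 genes with a mean of at least 2 FPKM, and 1055 and 1476 with limma on FPKM + 1 and + 0.5. A larger pseudocount shrinks fold changes of low genes by construction.

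GSDME was no longer called with library totals (log2 change 0.133, adjusted p = 0.0937), limma on FPKM + 1, + 0.5 and + 0.1 (0.11, 0.12 and 0.129) and TPM + 1 (0.018, adjusted p = 0.82); over its alternatives the adjusted p ran from 0.00123 to 0.82. MAPK14 was called lower in the same 5 settings (log2 change -0.16, -0.142, -0.151, -0.158 and -0.264). These settings lack the trimmed-mean factors and shift genes by a median of -0.10 to -0.21 log2. With fry, which does not compare a list with other genes, the pyroptosis (adjusted p = 0.000896, down), apoptosis (0.00592, up), PARP (0.000854, down) and p38 and JNK lists (5.14e-05, up) passed. Of the 37 lists tested, 34 passed with fry, so these calls are not particular to the routes that the title names. No omission of 1 library ended a call of a title gene or the camera call of the p53 list. The pyroptosis, apoptosis, PARP and p38 and JNK lists had no camera call to lose and passed in 0 of 6 omissions each. Their fry calls were not tested by omission, since fry was run on all 6 libraries only. Leaving out 1 library gave 5296 to 5681 higher and 5345 to 5663 lower genes. With the replicate number as a block, 5502 genes were higher and 5618 lower. Among lists that did not pass, proteasome and senescence-associated secretory genes each passed in 11 of 20 alternatives, with 3 and 5 of 6 omissions of a library among them, epithelial genes in 3 and autophagy genes in 2. Over all lists and alternatives, 659 comparisons with the main value were unchanged, 39 gained a call and 25 lost one. At this depth and spread, 80% of simulated 2-fold changes were found. The simulation left 15802 of 16082 genes unchanged, whereas 70% of genes were called in the data. Its recovery rate therefore does not carry over to the data, and it did not test the scaling when most genes move. Simulated genes were drawn independently of each other, so the simulated lists do not show how camera performs on lists whose genes are correlated. Smaller changes of low genes can still be missed.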

Other observations

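The gene families and terms in the first paragraphs were picked after the values had been seen, as were the tests of p53 targets, of the mitochondrial RNAs and of the components of RPL36A-HNRNPH2; the tests of single-exon genes, of read-through genes as a class, of gene length and of other splits were planned. Of 14 SR splicing factor genes 13 fell (median -1.64 log2): SRSF1 went from 36.2 ± 1.15 to 3.79 ± 0.593 FPKM and SRSF2 from 93.4 ± 4.36 to 11.9 ± 0.770 FPKM (SD, n = 3), while SRSF4 rose by 0.22 log2, a change of 0.00 as TPM. Of 24 hnRNP genes 18 fell and 3 rose (median -0.55 log2), with HNRNPA2B1 at -2.67 log2 and HNRNPC at 0.65 log2. The 4 CLK kinase genes, whose products phosphorylate SR proteins, rose (CLK1 by 1.17 log2). The KEGG spliceosome term, as the deposited table assigns it with pseudogenes and genes of other known functions, such as the ion channel gene NALCN and the endosome gene RAB5A, among its members, had 96 of 181 genes lower and 49 higher (camera adjusted p = 0.0274; adjusted p = 0.821 with an estimated correlation).

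Of 14 tubulin genes 12 fell and 1, TUBE1, rose (median -0.98 log2): TUBA1B went from 162 ± 4.42 to 26.2 ± 1.75 FPKM and TUBB4B from 205 ± 13.4 to 45.4 ± 2.28 FPKM (SD, n = 3); tubulins are near-identical, and reads shared between copies were not resolved. Of 16 host genes of small nucleolar RNAs 13 rose and 3 did not pass (median 1.24 log2), with SNHG7 at 1.96 log2. Of 1576 terms tested, 17 were called higher and 35 lower, and with an estimated correlation camera called 0 (smallest adjusted p = 0.821; 74 terms had an unadjusted p under 0.05). Among them ER to Golgi transport had 68 of 116 genes higher and 18 lower (adjusted p = 0.00218; adjusted p = 0.821 with an estimated correlation), with the coat protein gene SEC24D at 1.74 log2. Translational initiation had 25 of 39 higher and 4 lower (adjusted p = 0.0117; adjusted p = 0.834 with an estimated correlation), with EIF3D at 1.14 log2. Base excision repair had 25 of 36 lower and 6 higher (adjusted p = 0.0109; adjusted p = 0.821 with an estimated correlation), with the uracil glycosylase UNG at -1.28 log2.

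p53 target genes rose. Without the 3 genes shared with the ATF4, immediate-early, p38 and JNK or mesenchymal lists, 36 of 40 p53 targets rose. Camera still called the shortened list (adjusted p = 2.57e-14), so the call did not rest on those 3 genes alone. This could be foreseen, since 39 of 43 members had been seen to rise. It does not test a stress response that the lists share. Over all alternatives of the p53 list the adjusted p of camera or fry ran from 2.28e-29 to 0.0117. Genes shared with the apoptosis, pyroptosis and secretory lists, such as BBC3, NINJ1 and GDF15, stayed in, so their part was not tested. After a loess fit on GC content and exonic length, which explained 0.36% of the variance, the median of the list was 1.39 log2. A response of the cells to Japoflavone B is a candidate explanation, which mRNA data alone cannot test.

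Mitochondrial ribosomal RNAs rose while some mitochondrial mRNAs fell. A larger mitochondrial share that raises all transcripts alike would not by itself lower MT-CO3, at -0.66 log2 with 3 of 13 mRNAs lower. These values are part of the pattern and had been seen beforehand, so they are not a separate test. Weaker poly(A) selection, which could let in more RNA without tails, stays open. Small nucleolar RNAs had a median of -1.20 log2, with 5 tested, and small nuclear RNAs -0.43 log2, with 2 tested. Replication-dependent histones had 0.15 log2, or -0.60 as TPM, where the genes tested also differ. The 7SL RNA, with 1 gene tested, rose by 0.96 log2. Position along the heavy strand gave a Spearman correlation of -0.16 with fold change over 14 genes (permutation p = 0.57, 100000 resamples; genes are not independent replicates), too few genes to decide. A change in mitochondrial RNA processing or decay under Japoflavone B was not tested.

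The read-through gene RPL36A-HNRNPH2 was among the strongest increases of genes with a symbol and at least 5 FPKM. A rise of its component genes is not a likely source, since RPL36A and HNRNPH2 stood at 0.03 and 0.02 log2 against 6.71 for the read-through gene. A change in how reads are divided between the overlapping genes cannot be judged from these values. The read-through gene had 307 treated counts, and HNRNPH2 stood at 50.7 FPKM after treatment, so a small shift of reads need not move the component totals. A rise of single-exon over spliced genes, as impaired splicing might give, was not seen. The median of 208 single-exon genes lay at -0.07 log2 relative to 12408 genes with at least 3 exons (permutation p = 0.3). Genes are not independent replicates. Counts per gene do not show retained introns or skipped exons, so impaired splicing as such was not tested. Whether annotated read-through genes rise as a class stays open: the median of 164 was -0.15 log2, with a bootstrap interval of -0.24 to 0.15, and expression-matched random lists had -0.11. A biological change in transcript ends at this locus under Japoflavone B was not tested.

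Most genes changed. The Spearman correlation of fold change with genomic length, run as a test of blocked elongation in long genes, was -0.067 over 13029 protein-coding genes, which are not independent replicates. The 6 libraries can be split in 10 ways, so that no share under 0.05 can be had. The real split called 11263 genes and 3974 at least 2-fold, in both cases 1 of 10 splits with as many, and the highest of the others called 0 by edgeR, with up to 97 genes at an unadjusted p under 0.05. For gene lists, 2 of 10 splits called as many as the real one, 18, and the others called 13 to 18. Each of the other splits puts libraries of both treatments on either side, in unequal numbers. The treatment difference thus stays in the comparison and also widens the spread within each side. The splits therefore do not show what would be called without treatment, for genes or for lists.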
